A study of Homo sapiens with 16 samples.

How the data were processed

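The labels describe 16 libraries from 4 cultures of 293S cells: 12 Ago2 CLIP libraries, made with 3 antibodies from 2 untreated and 2 hippuristanol-treated cultures, and 4 RNA-seq libraries, 1 per culture. The antibody libraries of a culture are aliquots of the same material, so the culture is the replicate and there were 2 per treatment. The labels give 1 µM hippuristanol for 30 min. The table used here holds values for the peaks as a whole and not per library, so samples were not grouped or averaged here.

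The deposited table holds 4768 peaks with chromosome, start, end, strand, annotation class and gene. Per the file header, the values are scores that the authors normalized, a log average over hippuristanol and untreated cells and a log ratio of hippuristanol over untreated cells. The base of the logarithm, the kind of normalization, the peak caller, the filters and the way the libraries were pooled are not given in the sources used here. The values were examined for steps that would reveal a base of 2, 2.72 or 10, and none was found. A log ratio of 1 is a ratio equal to the base, so differences can be ranked but not turned into folds. Per the submitters' processing notes, Bowtie 0.12.8, TopHat and DESeq were used with the hg19 assembly, with no role or order given. The reference annotation used here was GENCODE 29 on GRCh38. Of 4546 peaks whose gene name it holds, 404 (8.89%) lay inside that gene's GRCh38 span, so the coordinates are not GRCh38 ones and are printed as the table gives them, as hg19. Whether starts are counted from 0 or 1 is not given. Peaks were 2 to 160 nt long with a median of 39 nt, and the RefSeq annotation was the source of 4691 and a catalogue of long intergenic RNAs of 27.

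Among the peaks there were 50 pairs with the same gene and identical values, 48 of them overlapping, and each pair was counted once, leaving 4718 distinct values in 2213 genes. A gene's value was the median of its peaks, which for the 1463 genes with 1 peak is the value of that peak. Depth per library is unknown, and no interval for counting error could be given. Medians have exact order-statistic intervals at 95%, and shares have exact Clopper-Pearson intervals, over peaks or genes as the items. These intervals treat peaks as independent, which overlapping peaks are not.

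The tests fixed before the data were examined assumed values per library, and the table holds scores pooled over libraries, so no test between treatments was run and no p-value is given. Gene lists were described by the percentile of their median among 10000 random lists of the same size, matched on log average in 10 bins, which compares genes within these pooled libraries. Classes of peaks were compared with 1000 random sets matched in the same way, and XIST, MALAT1 and NEAT1 with 1000 random sets of peaks without matching and with the medians of the genes with 5 or more peaks. Similarity within genes was measured by the one-way intraclass correlation, with 1000 bootstrap draws over genes and 1000 shuffles of peaks over genes. On simulated data of the same 4718 peaks, intraclass correlations set to 0.15 and 0.5 were recovered as 0.148 and 0.491. Simulated lists of 21 genes among the 2213 lay outside the central 95% of random lists in 8 of 100 cases with no shift, in 43 with a shift of 0.3 and in 84 with a shift of 0.5, so shifts near 0.3 in lists of that size were often missed.

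Named peaks were chosen by a rule fixed before the data were examined. It took the 10 peaks per direction with the largest log ratios, 1 per gene, the 5 peaks with the highest log average and up to 4 members of each gene list with the highest log average. The part of the rule that asked for an adjusted p and for the same direction in both replicate pairs could not be applied to pooled values. Some genes that the rule names are not reported here. Genes named for the median of 5 or more peaks, and list members named for their extremes, were chosen after the values were seen. The lists were ribosomal proteins and translation elongation, eIF4F and eIF4A cofactors, small RNA machinery, growth and survival mRNAs described as sensitive to eIF4A, stress and immediate early genes, cell cycle genes, described targets of let-7, miR-17, miR-15/16 and miR-19/92, replication-dependent histones, mitochondrially encoded genes and markers of other cell types.

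GC content, length and microRNA seed sites were taken from GENCODE 29 transcripts, matched by RefSeq identifier for 2151 genes and by symbol for 40, together 99.0% of the genes. They describe the annotated transcript or region, not the peak, because the sequence of hg19 was not used here. A seed site was the 7-nt match to positions in the seed of a microRNA family in the 3′ UTR of a gene with a 3′ UTR peak. Sets of genes with a site were compared with 1000 random sets matched on 3′ UTR GC content and length. The alternatives tried were all table rows, leaving out XIST, MALAT1 and NEAT1, leaving out peaks under 20 nt, centring on the gene median, 3′ UTR peaks only, 1 value per gene, peaks at least 50 nt apart or not overlapping, genes with 5 or more peaks, and other summaries and memberships of the lists. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.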

Results

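The series asks how the contacts between Argonaute 2 and messenger RNAs are rearranged when cells are stressed, here by hippuristanol. Argonaute 2 (Ago2) is the protein that carries microRNAs to their target transcripts. Hippuristanol is a natural product that blocks eIF4A, the RNA helicase that prepares the 5′ end of an mRNA for the ribosome, and so lowers the initiation of translation. The cells were 293S, an established human embryonic kidney cell line, left untreated or given 1 µM hippuristanol for 30 min. Per the labels, there were 2 cultures of each kind, and each culture was divided into 1 aliquot for RNA-seq and 3 aliquots for CLIP with Ago2 antibodies from 3 suppliers. CLIP crosslinks a protein to the RNA it touches, precipitates the protein and sequences the bound RNA. The labels thus describe 12 CLIP libraries, 6 per treatment, and 4 RNA-seq libraries, 2 per treatment.

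The values analysed were 1 log average and 1 log ratio of hippuristanol over untreated per Ago2 peak, pooled by the authors over libraries. The depth of each library is unknown, because the table holds no read numbers. The base of the logarithm is not given in the sources used here, so all values below are in the authors' log units and no folds are given. With 1 pooled value per peak, no difference between treated and untreated cells has a replicate check, and no test or p-value is given. Antibodies could not be compared, and RNA-seq values were not analysed here. Intervals of medians describe the spread over peaks or genes of this table, not the spread between cultures.

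Ago2 was found mainly on the 3′ untranslated regions (3′ UTRs) of mRNAs, where microRNAs usually bind. Of 4718 peaks with distinct values, 2894 (61.3%) lay in 3′ UTRs, 949 (20.1%) in coding sequence (CDS), 185 (3.92%) in 5′ UTRs and 690 (14.6%) in exons of non-coding RNAs. They fell in 2213 genes, of which 1463 had 1 peak and 160 had 5 or more. The long non-coding RNA XIST, which silences an X chromosome, had 296 peaks, more than MALAT1 with 126 or NEAT1 with 65, which are both nuclear RNAs. No peak was annotated to a mitochondrially encoded gene, and none of 13 marker genes of blood, liver, connective tissue, epithelial, glial or muscle cells had a peak. Whether the annotation held mitochondrial genes is not given, so their absence need not describe Ago2.

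The peaks with the highest log averages over both treatments lay in small nucleolar RNAs, in CHRNB2, in ARHGAP4 and in ANKRD30BL. SNORA74A, a small nucleolar RNA, had the highest log average in the authors' deposited table, 2.06, with a log ratio of 0.47. The peak in CHRNB2, a nicotinic acetylcholine receptor subunit of neurons, followed in the authors' deposited table with a log average of 1.48 and a log ratio of −2.09. The 3′ UTR peak of ARHGAP4 had a log average of 1.28 and a log ratio of −1.75 in the authors' deposited table. SNORA33 had 1.21 and −0.54, and the non-coding ANKRD30BL 0.34 and 0.01, as log average and log ratio in the authors' deposited table. The median log average over all peaks was −6.76, and XIST, with a median of −10.86 over its peaks, lay far below it.

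Across the transcriptome the log ratios were centred above 0. Their median over the 4718 peaks was 0.15 (95% interval 0.13 to 0.18), and 2787 peaks (59.1%, exact binomial interval 57.7% to 60.5%) lay above 0. A log ratio above 1 was listed for 535 peaks and one below −1 for 199 peaks, and 90% of the peaks lay between −0.96 and 1.29. The median of the gene medians was 0.17, which is used below as the level of an average gene. Whether this offset comes from the cells or from the authors' normalization is not recorded in the sources used here. Relative to that level, 334 peaks lay above 1 and 329 below −1, and 49.1% lay above it, a balance that the centring itself sets.

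The peaks with the highest log ratios included those in DEGS1, PDCD10, ATP5E and XIST. In the authors' deposited table the highest value, 3.18, was in the coding sequence of DEGS1, the dihydroceramide desaturase of ceramide synthesis (chromosome 1, 224377766 to 224377789, plus strand, hg19). The authors' deposited table listed 2.51 in the coding sequence of PDCD10, a protein of vascular malformations and vesicle transport (chromosome 3, 167405454 to 167405479, minus strand), and 2.36 in that of ATP5E, a subunit of ATP synthase (chromosome 20, 57605430 to 57605469, minus strand). In 3′ UTRs, the authors' deposited table listed 2.17 for BBIP1, a subunit of the ciliary BBSome (chromosome 10, 112660092 to 112660121, minus strand), and 2.16 for SLC17A5, a lysosomal sialic acid transporter. Further 3′ UTR peaks with high log ratios in the authors' deposited table were those of PPP1CC, a catalytic subunit of protein phosphatase 1, at 2.11, of ATP2A2, the calcium pump of the endoplasmic reticulum, at 2.11, and of LIMS1, an adaptor of focal adhesions, at 2.09. XIST also held a peak at 2.30 in the authors' deposited table, although the median of its 296 peaks was 0.16.

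The peaks with the lowest log ratios lay in CHRNB2, P4HB, PRRC2B, ANKRD52 and ARHGDIA, among the 10 genes named for them, which also included ARHGAP4. The lowest was the CHRNB2 peak named above (chromosome 1, 154544609 to 154544630, plus strand). CHRNB2 and ARHGAP4 had 1 peak each, and both peaks were also among the 5 with the highest log averages. In coding sequence, the authors' deposited table listed −2.01 for P4HB, a protein disulfide isomerase (chromosome 17, 79803782 to 79803816, minus strand), −1.97 for PRRC2B, and −1.73 for GNB2L1, the ribosome-bound scaffold protein RACK1. In 3′ UTRs, the authors' deposited table listed −1.90 for ANKRD52 (chromosome 12, 56633259 to 56633302, minus strand), −1.85 for ARHGDIA, −1.83 for the zinc finger gene ZNF224, −1.80 for EIF2S3, the gamma subunit of initiation factor eIF2, and −1.78 for JUN, an immediate early transcription factor (chromosome 1, 59247342 to 59247409, minus strand). A single peak did not stand for its gene in each case. PRRC2B had 7 peaks with a median of 0.24, above the level of an average gene, and ANKRD52 had 19 peaks with a median of −0.30.

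Peaks in 3′ UTRs, CDS and 5′ UTRs had similar medians of the log ratio, and peaks in non-coding exons a lower one. The median was 0.15 for 3′ UTR peaks, 0.20 for CDS peaks and 0.25 for 5′ UTR peaks. Among 1000 random sets of peaks of the same size, matched on log average, the CDS median stood at percentile 95.9 and the 5′ UTR median at percentile 95.6, both inside the central 95%. Among 234 genes with both kinds of peak, CDS peaks lay above 3′ UTR peaks in 123 and below in 111, with a median difference of 0.05 (95% interval −0.07 to 0.25). The CDS median was 0.04 above the 3′ UTR median over peaks, and with 1 value per gene the difference was −0.0042. Peaks in non-coding exons had a median of 0.08, at percentile 0.1 and so outside the central 95%. Their difference from 3′ UTR peaks was −0.08 (bootstrap 95% interval −0.15 to −0.01). It was −0.03 without XIST, MALAT1 and NEAT1, and −0.04 with 1 value per gene. Many non-coding peaks come from those 3 RNAs and are not independent. XIST and MALAT1 had low median log averages, −10.86 and −9.47, so sets matched on log average may redraw many of their peaks. The percentile is therefore not a comparison with other genes alone.

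**Figure D1:**
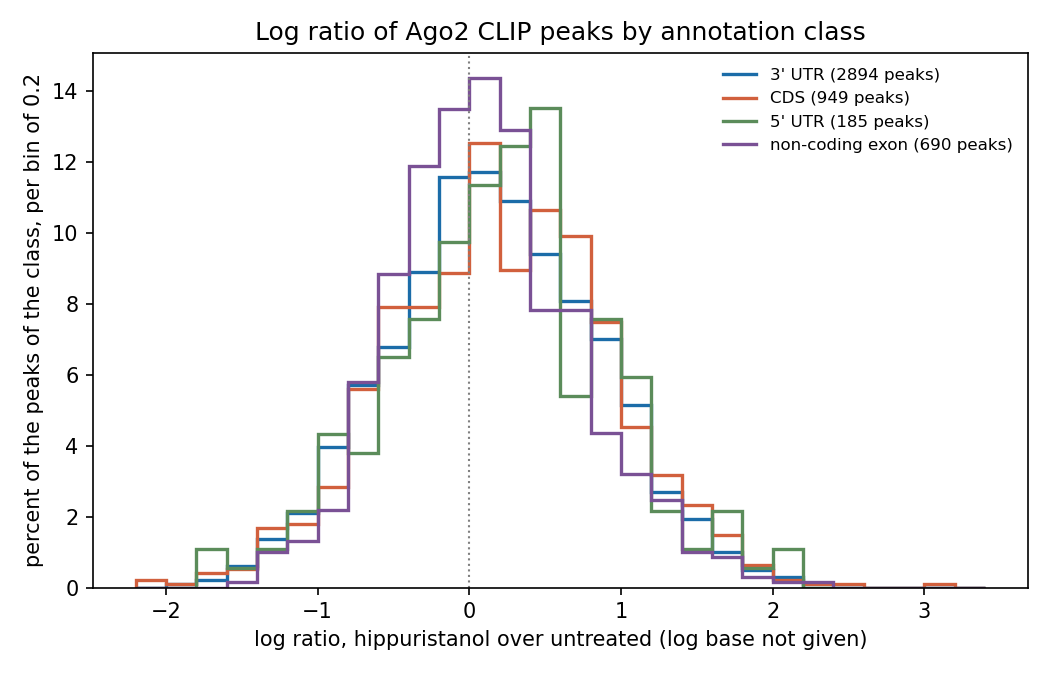
Distribution of the authors' log ratio of hippuristanol over untreated (horizontal axis, log base not given) as the percent of the peaks of each annotation class per bin of 0.2 (vertical axis). The lines are 3′ UTR, CDS, 5′ UTR and non-coding exon peaks, with medians of 0.15, 0.20, 0.25 and 0.08, and the dotted line marks 0.

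MALAT1 and NEAT1, long RNAs of nuclear speckles and paraspeckles, had medians below 0. The median over the 126 peaks of MALAT1 was −0.11 (95% interval −0.19 to −0.02), and 50 of them lay above 0. None of 1000 random sets of as many peaks, drawn from all peaks, had a median as low, and 36 of the 160 genes with 5 or more peaks, most with far fewer peaks than MALAT1, had a lower median. NEAT1 had a median of −0.05 over 65 peaks (95% interval −0.22 to 0.06), at percentile 2.3 of such sets, and 45 of the 160 genes had a lower one. XIST had a median of 0.16 over its peaks (95% interval 0.08 to 0.22), at percentile 60.9, with 70 of the 160 genes lower. The 84 small nucleolar and Cajal body RNA genes had a median of 0.21, at percentile 79.4 of lists matched on log average, and a median log average of −4.82 against −6.33 for all other genes. Peaks of a single RNA are not independent, so the intervals of MALAT1, NEAT1 and XIST are too narrow and their percentiles too extreme.

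Gene lists fixed in advance were compared by the median of their members' gene medians, set against 10000 random lists of the same size matched on log average. Of 8 lists with at least 5 measured members, 2 lay outside the central 95% of their random lists, where 0.4 would be expected by chance. These were the replication-dependent histones, below, and the described targets of let-7, miR-17, miR-15/16 and miR-19/92, above.

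Histone mRNAs, which are made for DNA replication and end in a stem-loop in place of a poly(A) tail, had low log ratios. The median over 21 histone genes was −0.36 (95% interval −0.79 to 0.04), at percentile 0.11, and 17 of the 21 lay below the level of an average gene. The list's median minus that of all genes was −0.53, and −0.32 with 3′ UTR peaks only. Of the members with the highest log averages, HIST1H3H had a gene median of −0.81, HIST1H3A of 0.02, HIST3H2A of 0.20 and HIST1H3B of 0.61. All but HIST1H3A had 1 peak, as had HIST1H2AG and HIST1H4E below. The lowest, chosen after the values were seen, were HIST1H2AG with a gene median of −1.25, HIST1H4E with −1.10, and below them HIST1H2AC, whose peaks had −1.72 and −1.27 in the authors' deposited table. Many histone genes are near-identical copies, so their peaks may share reads and the value of a single copy is uncertain.

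The described targets of these microRNAs had high log ratios by gene. The median over 22 genes was 0.53 (95% interval −0.20 to 0.75), at percentile 98.9, and 16 of the 22 lay above the level of an average gene. Among the members with the highest log averages, CPEB3, a regulator of mRNA polyadenylation, had a gene median of 0.80, SMAD7, an inhibitor of TGF-beta signalling, of 0.75, BAMBI, a decoy receptor of that pathway, of 0.52, and TRIM71, a let-7 target of stem cells, of −0.76. The highest and lowest of the others, chosen after the values were seen, were CPEB4 at 1.40 from 1 peak and the proapoptotic BCL2L11 at −0.42 from 14 peaks. CPEB3, SMAD7 and TRIM71 also had 1 peak each, that of SMAD7 in coding sequence, so their values are those of single peaks. Pooled over peaks, which gives genes with many peaks such as ANKRD52 and BCL2L11 more weight, the list's median minus that of all peaks was −0.04. By gene, the difference from all genes was 0.36 with medians and 0.23 with means.

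Genes of ribosomal proteins and translation elongation had a median below the level of an average gene, inside the range of random lists. Their 42 genes had a median of −0.01 (95% interval −0.18 to 0.22), at percentile 4.47, and 25 lay below the level of an average gene. Of the members with the highest log averages, RPL10 had a gene median of 0.22, RPS15 of −0.61, RPLP1 of −0.48 and RPL12 of 1.13. RPL10, RPS15 and RPL12 had 1 peak each. By its rule the list also took in the kinases RPS6KB1 and RPS6KC1, and ribosomal protein genes have many pseudogenes that may share their reads. The list's median minus that of all genes was −0.18, and −0.20 without these kinases. With 3′ UTR peaks only it was −0.33. These alternatives were not compared with random lists.

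The other lists lay well within the range of their random lists. The small RNA machinery had a median of 0.42 over 12 genes, at percentile 87.2, and 9 of the 12 lay above the level of an average gene. The list's median minus that of all genes was 0.248, and 0.125 with 3′ UTR peaks only. In that list EIF2C2, which encodes Ago2 itself, had a gene median of 0.04, LIN28B, which blocks let-7 maturation, of 0.65, TNRC6C, a partner of Argonaute in silencing, of −0.45, and CNOT6, a deadenylase, of −0.71. The eIF4F and eIF4A cofactor genes, closest to the target of hippuristanol, had a median of 0.31 over 7 genes, at percentile 68.3. EIF4A2 stood at 0.31, PDCD4, an inhibitor of eIF4A, at 0.37, EIF4EBP2 at 0.21 and EIF4E2 at −0.39. EIF2C2, EIF4A2, PDCD4 and EIF4E2 had 1 peak each.

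Cell cycle genes had a median of 0.26 over 20 genes, at percentile 76.9, and 15 lay above the level of an average gene. The cyclin-dependent kinase inhibitors CDKN1A and CDKN1B had gene medians of 0.39 and 0.23, and the transcription factor E2F1 of −0.50. Growth and survival mRNAs described as sensitive to eIF4A had a median of 0.13 over 9 genes, at percentile 41.1, with MYC at −0.05, CCND1 (cyclin D1) at −0.09, VEGFA at −0.73 and XIAP at 0.33. Stress and immediate early genes had a median of 0.12 over 16 genes, at percentile 45.1. Their members with the highest log averages were JUND at 0.15, JUNB at −0.15, IER5 at 0.90 and the antiproliferative BTG1 at 1.21. VEGFA, JUNB and BTG1 had 1 peak each. HSPA1A and HSPA1B, heat shock genes of similar sequence, stood at 0.39 over 6 peaks and 0.41 over 10 peaks, none of them in coding sequence. Reads shared between the genes were not tested, so their values may not be separate measurements.

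**Figure D2:**
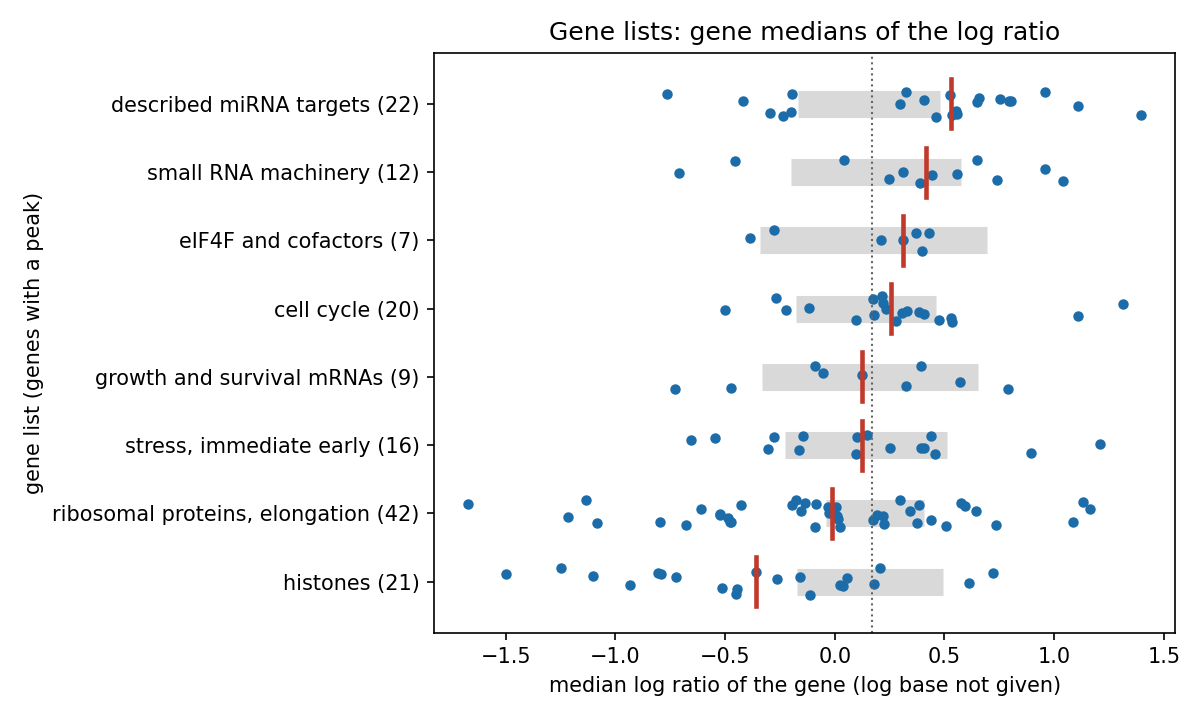
Gene medians of the log ratio of hippuristanol over untreated (horizontal axis, log base not given) for the members of 8 gene lists, with the number of genes in brackets. Points are genes, red lines list medians, grey bars the central 95% of 10000 random lists matched on log average, and the dotted line the median of all genes, 0.17. The histones at −0.36 and the described microRNA targets at 0.53 lie outside their grey bars.

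Peaks of the same gene had more similar log ratios than peaks of different genes, but most of the variation lay within genes. The intraclass correlation of the log ratio over 750 genes with 2 or more peaks was 0.146 (bootstrap 95% interval 0.113 to 0.183), where shuffling peaks over genes 1000 times gave at most 0.0487. For the log average it was 0.906. Part of the similarity came from peaks that overlap and so share reads. Neighbouring peaks that overlapped correlated with Pearson's r of 0.583 over 474 pairs, those up to 49 nt apart with r of 0.181, and those 3000 nt or more apart with r of 0.00712. These are correlations across pairs of peaks, which are not independent replicates. Without overlapping peaks the intraclass correlation was 0.115.

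High gene medians were more frequent than after shuffling, but few genes had all their peaks on the same side. Among the 160 genes with 5 or more peaks, 17 had a median more than 0.5 above the level of an average gene, against a mean of 8.32 and a central 95% of 4 to 14 after shuffling. More than 0.5 below it were 12 genes, against 8.18 and 3 to 14, so the lower side did not stand apart. Shuffling moved peaks singly, although overlapping peaks share reads, and these counts were not repeated without overlapping peaks. How much of the excess of high medians comes from overlap is therefore unknown. Every peak lay above the median of all peaks in 3 of the 160 genes, against a mean of 1.91 (0 to 5) after shuffling, and below it in 5, against 2.03 (0 to 5), neither outside the shuffled range. Named here for their medians, after the values were seen, ATP2A2 had the highest median, 1.28 over 6 peaks, followed by CLPTM1 at 1.06, the Wnt receptor FZD6 at 0.95, VMA21, an assembly factor of the vacuolar ATPase, at 0.92, PPP1CC at 0.90 and the intermediate filament gene VIM at 0.87. In the authors' deposited table the 6 peaks of CLPTM1, 4 in coding sequence and 2 in the 3′ UTR, lay between 0.72 and 1.28. MCL1, an antiapoptotic gene, had a median of 0.79 over 11 peaks. The lowest medians were those of LONRF1 at −0.80, ARHGDIA at −0.54, the Polycomb genes CBX6 at −0.53 and JARID2 at −0.50, and the splicing factor SRSF2 at −0.48. BCL2L11 had 13 of its 14 peaks below 0.

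Within LONRF1 and ARHGDIA, peaks of opposite sign lay close together. In the authors' deposited table the 6 peaks of the LONRF1 3′ UTR (chromosome 8, between 12580064 and 12580602, minus strand) ranged from −1.38 to 1.02. In the authors' deposited table the 3 ARHGDIA peaks between 79825596 and 79825723 on chromosome 17 had −0.11, 0.24 and 0.55, and the overlapping pair between 79826254 and 79826343 had −1.73 and −1.16. Another overlapping pair, between 79826490 and 79826605, had opposite signs, 0.17 and −1.85, in the authors' deposited table. Over all genes with 5 or more peaks, 23 held both a peak above 1 and a peak below −1, where shuffling gave a mean of 31.4 (24.0 to 40). The count thus lay just below the shuffled range. Shuffling separates overlapping peaks, which often but not always have similar values, and the count was not repeated without them.

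**Figure D3:**
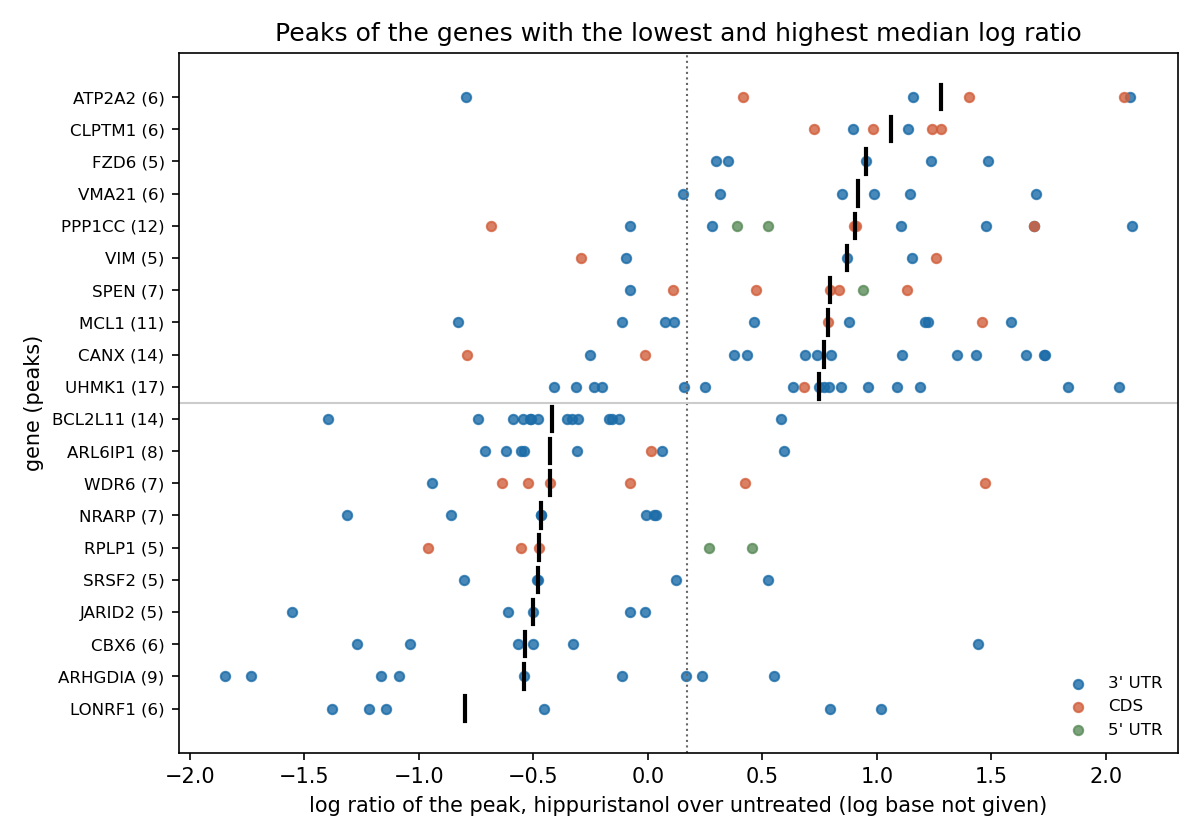
Log ratio of each peak (horizontal axis, log base not given) for the 10 genes with the highest and the 10 genes with the lowest median among 160 genes with 5 or more peaks, with the number of peaks in brackets. Points are single peaks coloured by annotation class, black lines gene medians, and the dotted line the median of all genes, 0.17. The 6 peaks of CLPTM1 lie between 0.72 and 1.28, while those of LONRF1 range from −1.38 to 1.02.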

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

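All alternatives given here were chosen after seeing the data. The alternatives fixed before the data were examined, which concern count normalization, low-count filters, other tools, antibodies, left-out libraries and seed sites within peaks, were not run, because the table holds 1 pooled value per peak and the hg19 sequence was not used here. No paired analysis was possible because the table holds no values per replicate. Of 92 alternative values for 17 results, 3 left the main value's 95% interval (for counts, 1.5 times), and 1 more changed the sign of a list outside its random range while inside that list's wide interval. The other 88 stayed within these bounds. Centring on the gene median moved the share of peaks above 0 from 59.1% to 49.1%, the peaks above 1 from 535 to 334 and those below −1 from 199 to 329, by its own construction. Pooling all peaks turned the described microRNA targets from 0.36 above the median of all genes to a difference of −0.0432 from all peaks, because genes with many peaks then weigh more. Of the 88, another 7 changed sign within intervals that include 0, for the CDS against 3′ UTR difference and for the lists of eIF4F cofactors, growth and survival mRNAs and stress genes, so no direction is given for these. The unknown depth leaves open how much of the spread of single peaks is counting error.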

Other observations

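The tests of GC content, length, peak number and seed sites were set before their results were seen, while the match on GC content and length together, the test of peak number against log average and the descriptions of histone types and GC trends were chosen only after values were seen. By type, the histone genes are given here as values only, since differences between types were not tested and most genes have 1 or 2 peaks. The core histone H2A genes had a median of −0.79 over 7 genes, and 6 of the 7 lay below 0. All 4 histone H4 genes lay below 0, with a median of −0.48, and the 4 H2B genes had a median of −0.26. The 4 histone H3 genes spread from −0.81 for HIST1H3H to 0.72 for HIST1H3I, with a median of 0.32, and the 2 linker histone genes HIST1H1C and HIST1H1E stood at 0.18 and 0.06.

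Genes whose bound region was rich in G and C had lower log ratios. Among 1526 genes with 3′ UTR peaks, the fifth with the highest 3′ UTR GC content (51.0% to 83.3%) had a median of −0.03, against 0.22 in the fifth with the lowest (22% to 33.6%) and 0.33 in the next. Spearman's rho across genes was −0.152 (bootstrap 95% interval −0.20 to −0.10). Among 693 genes with CDS peaks the median went from 0.24 in the fifth with the lowest CDS GC content to −0.02 in the highest, with rho of −0.160 (−0.235 to −0.0860). For 144 genes with 5′ UTR peaks rho was −0.0983 (−0.260 to 0.0657), and for 116 non-coding genes 0.0537 (−0.134 to 0.238), both with intervals that include 0. Genes are not independent replicates in these correlations.

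The low log ratios of the histone genes were weighed against properties of their transcripts, which are short, with a median of 503 nt against 3388 nt for all genes, and have a median GC content of 57.5% against 46.9%. Matched on GC content, the list's median stood at percentile 0.725 of 10000 random lists, and matched on length at percentile 0.28. Matched on both together, it stood at percentile 1.28. The match on GC content argues against GC content alone as the whole cause. The matches that include length cannot exclude length, because they used broad bins, 10 for length alone and 5 of each property for both. The random lists of all these matches also drew on non-coding genes, such as the small nucleolar and Cajal body RNA genes with a median of 0.21. Reads shared between near-identical histone genes and the authors' normalization were not tested and remain open. An effect of hippuristanol on Ago2 contacts of histone mRNAs may also be involved and has no replicate check.

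The high gene medians of the described microRNA targets were weighed in the same way. The list stood at percentile 98.57 when matched on GC content, 98.93 on length and 99.7 on the number of peaks per gene. Matched on GC content and length together, it stood at percentile 98.99. The match on GC content argues against GC content alone as the whole cause. The list's median length was 5859 nt against 3388 nt for all genes, and its median number of peaks 2 against 1. The matches that include length or peak number used broad bins, so they cannot exclude these properties. The pattern is less firm than these percentiles look, since the list was 1 of 8 compared, its median has a 95% interval from −0.20 to 0.75, and it had a difference of −0.04 from all peaks when its peaks were pooled. A link to microRNA targeting is a hypothesis that was examined further with seed sites.

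The prediction set was that, if targeting by a microRNA taken to be expressed went with a different log ratio, several of 17 families would stand apart by their 3′ UTR sites. The number of families outside the central 95% of sets matched on GC content and length was 1, with 0.85 expected by chance. That family was miR-21, with a median of 0.32 over 193 genes with a site, at percentile 99.1. Sites of let-7 stood at percentile 92.2 with a median of 0.23 over 190 genes, sites of the miR-17 family at percentile 82.5, sites of the miR-25/92 family at percentile 73.8 and sites of miR-15/16 at percentile 55.2. Sites of miR-19 stood at percentile 30.1, with a median of 0.16 with a site and 0.16 without. Among 3 families chosen for comparison because they are usually low in cells of kidney origin, sites of miR-124 stood above all 1000 matched sets. Their median was 0.30 over 283 genes. Genes with a site can thus stand apart for a family not taken to be expressed, so the miR-21 value cannot be read as targeting. The level of these microRNAs in the cells was not analysed here. With 6-nt sites none of the 17 lay outside. These are sites anywhere in the 3′ UTR, and sites within peaks were not analysed here. All genes compared had a 3′ UTR peak, with or without the site, and the power of the comparison was not measured. The prediction was not met, but the count cannot decide for or against a link to microRNA targeting.

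The log average was almost a property of the gene, with an intraclass correlation of 0.906, and XIST and the 42 ribosomal protein and elongation genes, with medians of −10.86 and −7.28, had low values against −6.30 for all genes. A candidate explanation is that each peak was divided by the RNA level of its gene, which would put abundant transcripts low. Some members of that list lay high, such as RPL10 at −2.56 and RPS15 at −3.13. The small nucleolar and Cajal body RNA genes had a median of −4.82 against −6.33 for all other genes. RNA levels were not analysed here, so whether these values go against the explanation is unknown. Genes with more peaks had lower log averages, with Spearman's rho of −0.204 across 2213 genes (bootstrap 95% interval −0.244 to −0.162), the direction this explanation needs. Other scalings, such as by the Ago2 signal of the whole gene, were not tested and remain open. If so, the log ratio would be the Ago2 signal relative to the RNA, and a gene's RNA level could enter both its numerator and its denominator. The log ratio itself had almost no relation to the log average, with rho of −0.0260 across peaks. That value does not measure the spread of the log ratio at the highest log averages, where such a division would put scarce transcripts. CHRNB2 and ARHGAP4, with log ratios among the lowest, lay there, and that spread was not tested.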
